A study of Homo sapiens with 19 samples.

How the data were processed

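Total RNA of the K-562 cell line was profiled with 5 methods for RNA 5′ ends and with standard RNA-seq, in 19 samples and 22 deposited lists (21 cluster lists and 1 RNA-seq list). Groups, replicate numbers and inputs were taken from the labels. The submitters' processing notes name the build hg19 and the tools STAR 2.4.2a, Cufflinks 2.2.1 and TopHat, with no version for TopHat and no role for any of them. The cluster names in the files carry the name of Paraclu, a program that groups neighbouring 5′ tag positions. Its settings are not given in the sources used here. Per the labels, the CAGE list at 20M reads pools replicates 1, 4 and 6, and those of RAMPAGE and STRT come from replicate 1. All other lists are of 1 library.

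Each deposited cluster has a score whose definition is not given in the sources used here. In 20 of the 21 cluster lists the authors' score is a whole number from 200 to 1000. The cluster numbers of these lists have gaps, so that clusters had been removed after numbering by a rule that is not given. The highest number plus 1 was taken as a lower bound of the clusters numbered. In the oligo capping list the deposited score runs from 61 to 1897234, the numbers have no gaps, and clusters on mitochondrial DNA and unplaced contigs are present. This list was therefore selected differently from the others, which limits its comparison with them. No cluster in any list is wider than 299 bp. The RNA-seq list holds 20210 windows of 200 bp with a decimal value, treated as a score since its unit is not given. Windows given more than once (3933) were kept once with their highest value, which left 16277.

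The files hold no read counts. The depth behind a cluster is unknown, and the nominal depths, taken from the deposited names, are 20, 7, 6.4 or 5 mega-reads (M). Those of the titration libraries are unknown. Scores were used to rank and filter clusters within a list. In addition, thresholds at the median score pooled over libraries (401 in the titration, 489 over CAGE and STRT) served as alternatives, and the median score of each titration list was set against input. Scores of named regions were also averaged over the libraries of a method. These uses assume a scale shared by the lists, which the sources used here do not give. CAGE at 7M and RAMPAGE and STRT at 5M reads were compared as deposited. No count model was used.

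Clusters were compared on the same strand, with an overlap of at least 1 bp, and by the Jaccard index of covered bases. Shares of a single list have 95% Wilson intervals. Numbers per library were compared by two-sided exact permutation tests of the difference in means, and method separation by relabelling the 8 libraries. Correlations with the logarithm of input were tested by exact permutation of the pairings, except that with 10 libraries 100000 resamples were drawn. Benjamini-Hochberg adjustment covered 6 measures for each pair of methods, the 4 planned titration measures, and 7 when those added later were included. For recovery by RNA-seq value the unique windows were divided into 10 groups of about equal size, the highest holding 1628 windows with values of 18.4 or more. The lower 50% held 8139 windows with values up to 2.52. Regions across libraries were the union of the overlapping clusters of 16 libraries on chromosomes 1 to 22 and X.

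Regions were named by chromosome, start, end (counted from 1) and strand, by a rule set before the data were examined: the 3 of highest score in each list at 20M reads, the 5 CAGE clusters of highest score found in every CAGE and no STRT library, and the reverse for STRT. Ties were broken by width and position. No annotation of build hg19 was used here, and the files name no genes. The planned share near annotated transcript starts and the planned detection of gene lists were therefore not run, and no gene lists or cell type markers are reported. Replicates of the same group were compared, and no 2 lists held the same regions.

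The replicate numbers of the titration were checked for pairing from the presence of regions. The deviations of same-numbered libraries of 1, 5 and 10 µg correlated at -0.026, 0.001 and 0.022, so that the numbers were not treated as pairs. Alternatives changed the overlap required, the extension of clusters (50 bp), their merging (100 bp), the score threshold, the strand rule, the number of clusters per list and the libraries included. The interval and permutation code was tested on simulated data: 20 of 20 simulated pairs of sets of 400 regions gave the same counts as bedtools, and 4.0% of 400 null simulations of 4 against 10 libraries fell at or below 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.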

Results

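The study set 5 methods for sequencing the capped 5′ ends of RNA beside each other on total RNA from K-562, an established human cell line derived from chronic myeloid leukemia. CAGE traps capped RNA through a biotin tag on the cap. RAMPAGE joins cap trapping to template switching, and STRT relies on template switching during reverse transcription. Oligo capping replaces the cap with an RNA oligonucleotide, and NanoCAGE-XL is a template-switching form of CAGE. A strand-specific RNA-seq library, made after depletion of ribosomal RNA, was the control. The 19 samples comprised 3 CAGE libraries from 10 µg RNA and 1 from 5 µg, 2 RAMPAGE libraries from 5 µg, and 2 STRT libraries from 10 ng. Oligo capping (40 µg), NanoCAGE-XL (7.5 µg) and the RNA-seq control (1 µg) had 1 library each. A second set of 8 STRT libraries covered inputs of 10 ng and 100 ng (1 library each) and of 1, 5 and 10 µg (2 libraries each).

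Each sample of the 5 methods was represented by a list of 5′ end clusters, and the RNA-seq control by windows of 200 bp. Clusters are short stranded stretches of the genome (build hg19) where read starts gathered. The nominal depth, in mega-reads (M), was 20M reads for 1 list each of CAGE, RAMPAGE, STRT, oligo capping and RNA-seq. It was 7M reads for the 4 CAGE libraries, 5M for the RAMPAGE and earlier STRT libraries and 6.4M for NanoCAGE-XL. The depth of the 8 titration libraries is unknown. Every library came from the same commercial source of RNA, so that p-values measure only the spread between libraries, which may be technical. Intervals given for shares are 95% Wilson intervals and cover counting error only.

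The first comparison asked how many 5′ ends each method yielded at the same nominal depth. At 20M reads CAGE yielded 10323 clusters, RAMPAGE 8763, oligo capping 8191 and STRT 5412. NanoCAGE-XL yielded 1372 at its lower depth. The median cluster width was 165 bp in CAGE, 129 bp in RAMPAGE, 146 bp in STRT, 127 bp in oligo capping and 151 bp in NanoCAGE-XL. The clusters covered 1764 kb in CAGE, 1269 kb in RAMPAGE, 850.3 kb in STRT, 1172 kb in oligo capping and 218 kb in NanoCAGE-XL. Both strands held similar shares of the clusters, with 50.7% of the CAGE clusters and 50.8% of the STRT clusters on the plus strand. There was 1 list per method, so these counts have no replicate check.

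Among the separate libraries of the 3 methods with replicates, CAGE again held the most clusters and STRT the fewest. The CAGE libraries were at 7M reads, and the RAMPAGE and 2 of the STRT libraries at 5M. The 4 CAGE libraries held 10433 ± 263 clusters (mean ± SD, n = 4), against 4864 ± 272 in the 10 STRT libraries, a difference of 5569 clusters. The 2 RAMPAGE libraries lay between them, with 8819 ± 148 clusters (n = 2). Every CAGE library exceeded every STRT library, and the two-sided exact permutation test over 1001 splits gave p = 0.001 for CAGE against STRT, the smallest value it can give (0.0012 after Benjamini-Hochberg adjustment over 6 measures). The STRT libraries form 2 sets, and the difference was 5561 clusters against the 8 titration libraries (exact permutation p = 0.002). Against the 2 STRT libraries at 5M reads it was 5600 clusters, where the exact permutation test cannot go below p = 0.0667, the value it gave. RAMPAGE held fewer clusters than CAGE by 1615 on average, a difference larger than the SD of either group, with an exact permutation p of 0.0667, again the smallest that 2 against 4 libraries allow. All these counts are of listed clusters, after the authors' removal. The listed share of numbered clusters was 91.85% ± 2.19 in CAGE (n = 4) and 65.58% ± 6.72 in STRT (n = 10). The clusters numbered, a lower bound, were 11366 ± 467 and 7454 ± 407, a smaller difference that was not tested. Part of the difference in listed clusters may therefore come from the removal.

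**Figure D1:**
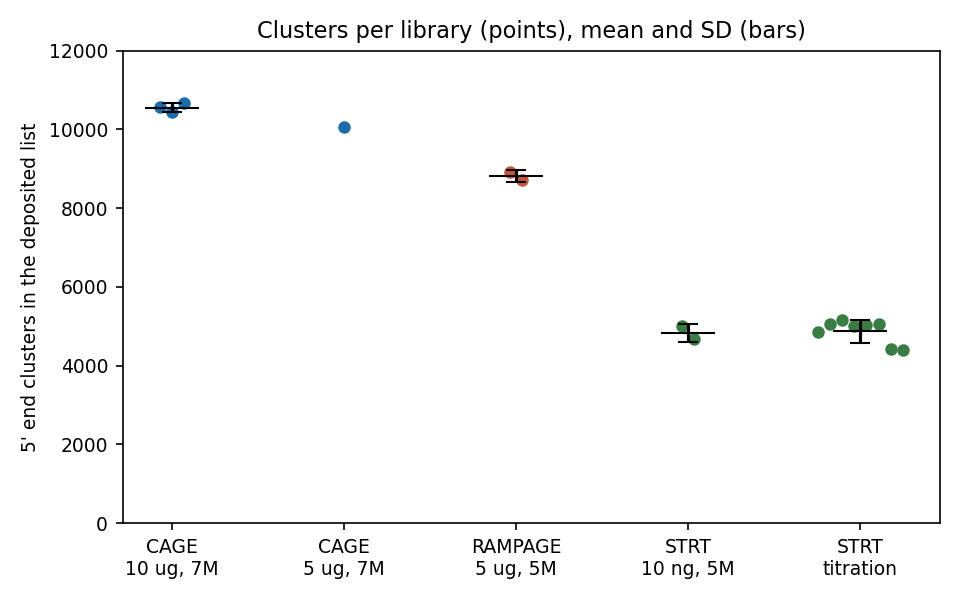
Number of 5′ end clusters per library (vertical axis) for each method, input and nominal depth (horizontal axis); points are libraries, and bars give the mean and SD of sets of 2 or more. The 4 CAGE libraries lie between 10063 and 10668 and the 10 STRT libraries between 4394 and 5150.

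The second comparison asked which 5′ ends the methods shared. Nearly all STRT clusters at 20M reads overlapped a CAGE cluster on the same strand (98.4%, interval 98.0 to 98.7), and 87.3% (86.4 to 88.2) overlapped a RAMPAGE cluster. In the other direction STRT covered 51.6% (50.7 to 52.6) of the CAGE clusters. RAMPAGE clusters overlapped CAGE clusters in 84.7% (83.9 to 85.4) of cases and covered 71.8% (70.9 to 72.6) of them. Of the oligo capping clusters, 54.4% (53.3 to 55.4) overlapped a CAGE cluster, 52.5% (51.5 to 53.6) a RAMPAGE cluster and 44.4% (43.3 to 45.4) an STRT cluster. NanoCAGE-XL, with the shortest list, lay on CAGE clusters in 99.2% (98.6 to 99.6) of cases and covered 13.2% (12.6 to 13.9) of them.

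In the oligo capping list the share of clusters that also lay on clusters of CAGE or STRT rose with the score. The list was selected differently from the others, so that an effect of the method cannot be told apart from the selection. It was the only cluster list with scores above 1000, running from 61 to 1897234. In the lowest quartile of that score 31.7% of 2056 clusters overlapped a CAGE cluster, and the next quartiles gave 43.3%, 59.9% and 82.7%. Overlap with STRT ran from 21.5% in the lowest to 76.1% in the highest quartile. Taking the upper 50% of the list by score, an alternative chosen after seeing the data, gave an overlap of 71.2% with CAGE. When each list was limited to its 5412 clusters of highest score, the overlap with CAGE was 34.9% for oligo capping, 52.5% for STRT and 56.9% for RAMPAGE. The STRT list holds 5412 clusters in full, so for STRT the limit shortened only the CAGE list, from 10323 clusters. Against the full CAGE list the STRT overlap was 98.4%. The lower STRT share therefore comes from the shorter CAGE list, and the limited shares do not rank the methods by sharing with CAGE.

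Windows of 200 bp with an RNA-seq value served as the control. CAGE clusters lay on such a window in 69.8% (68.9 to 70.7) of cases, RAMPAGE clusters in 61.9% (60.8 to 62.9), STRT clusters in 74.2% (73.0 to 75.3), oligo capping clusters in 39.4% (38.3 to 40.4) and NanoCAGE-XL clusters in 74.9% (72.5 to 77.1). For the 5412 CAGE clusters and the 5412 windows of highest score or value the share was 39.1%. Over the separate libraries the share was 69.1% ± 0.21 in CAGE (n = 4), 60.7% ± 0.18 in RAMPAGE (n = 2) and 73.9% ± 0.28 in STRT (n = 10). STRT exceeded CAGE in every pair of libraries (exact permutation p = 0.001, two-sided). STRT also exceeded RAMPAGE in every pair (exact permutation p = 0.0152, the smallest that 66 splits allow). The STRT lists are shorter, and this share was not compared between methods at equal numbers of clusters. Regions of every CAGE and every STRT library held a window in 80.2% of cases. Those of every CAGE and no STRT library held one in 68.2%, and were narrower (median width 229 against 287 bp).

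The methods differed in how their coverage of RNA-seq windows followed the RNA-seq value. In the highest decile of the 16277 windows CAGE recovered 79.4% ± 0.19 (n = 4), RAMPAGE 66.0% ± 0.44 (n = 2) and STRT 63.9% ± 1.89 (n = 10). The difference of 2.03 percentage points between RAMPAGE and STRT did not pass the test (exact permutation p = 0.136, two-sided). In the lower 50% of windows CAGE recovered 28.9% ± 1.30, RAMPAGE 23.2% ± 0.43 and STRT 9.65% ± 0.78. In the lowest decile RAMPAGE (10.9% ± 0.13) and CAGE (10.8% ± 0.64) differed by less than the spread between libraries, and STRT reached 2.92% ± 0.24. The exact permutation test for CAGE against STRT gave p = 0.001 in both the highest decile and the lower 50%, and that for RAMPAGE against STRT gave p = 0.0152 in the lower 50%. Within the STRT sets, the lower 50% gave 9.09% ± 0.63 for the 2 libraries at 5M reads and 9.79% ± 0.79 for the 8 titration libraries. The comparison by RNA-seq value was chosen after seeing the data. The STRT lists are shorter, and recovery was not compared at equal numbers of clusters.

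**Figure D2:**
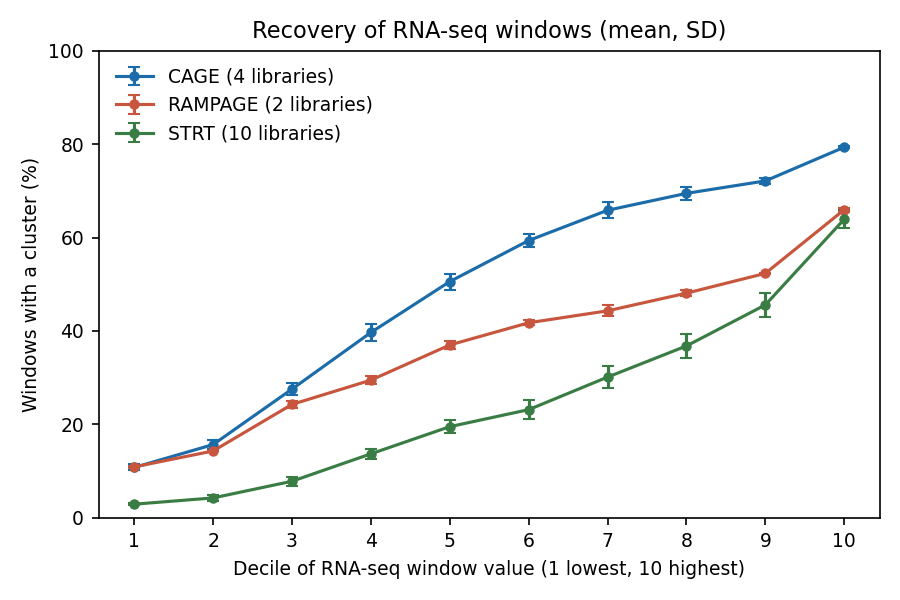
Share of RNA-seq windows with a cluster (vertical axis, percent) in each decile of RNA-seq value (horizontal axis, 10 the highest); points are means over libraries and bars SDs. STRT rises from 2.92% to 63.9%, RAMPAGE from 10.9% to 66.0% and CAGE from 10.8% to 79.4%.

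The third comparison asked whether libraries of 1 method shared more of their bases than libraries of different methods. The mean Jaccard index, the shared bases over all bases covered by either library, was 0.641 for pairs within a method and 0.354 for pairs between methods, over 8 libraries at reduced depth. The difference of 0.287 was the highest among 210 ways of assigning the labels (exact permutation p = 0.0048, two-sided). The index was 0.667 to 0.669 among the 3 CAGE libraries of 10 µg, 0.581 for the RAMPAGE pair and 0.615 for the STRT pair from 10 ng. It was 0.396 on average between CAGE and RAMPAGE, 0.323 between CAGE and STRT, and 0.332 between RAMPAGE and STRT. Unequal covered length limits the index between methods, with 709 kb in the STRT libraries of 10 ng and 1609 kb in CAGE on average. The difference within minus between methods was 0.229 with equal numbers of clusters. By the share of clusters shared it was 0.208 (exact permutation p = 0.0048 for each).

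**Figure D3:**
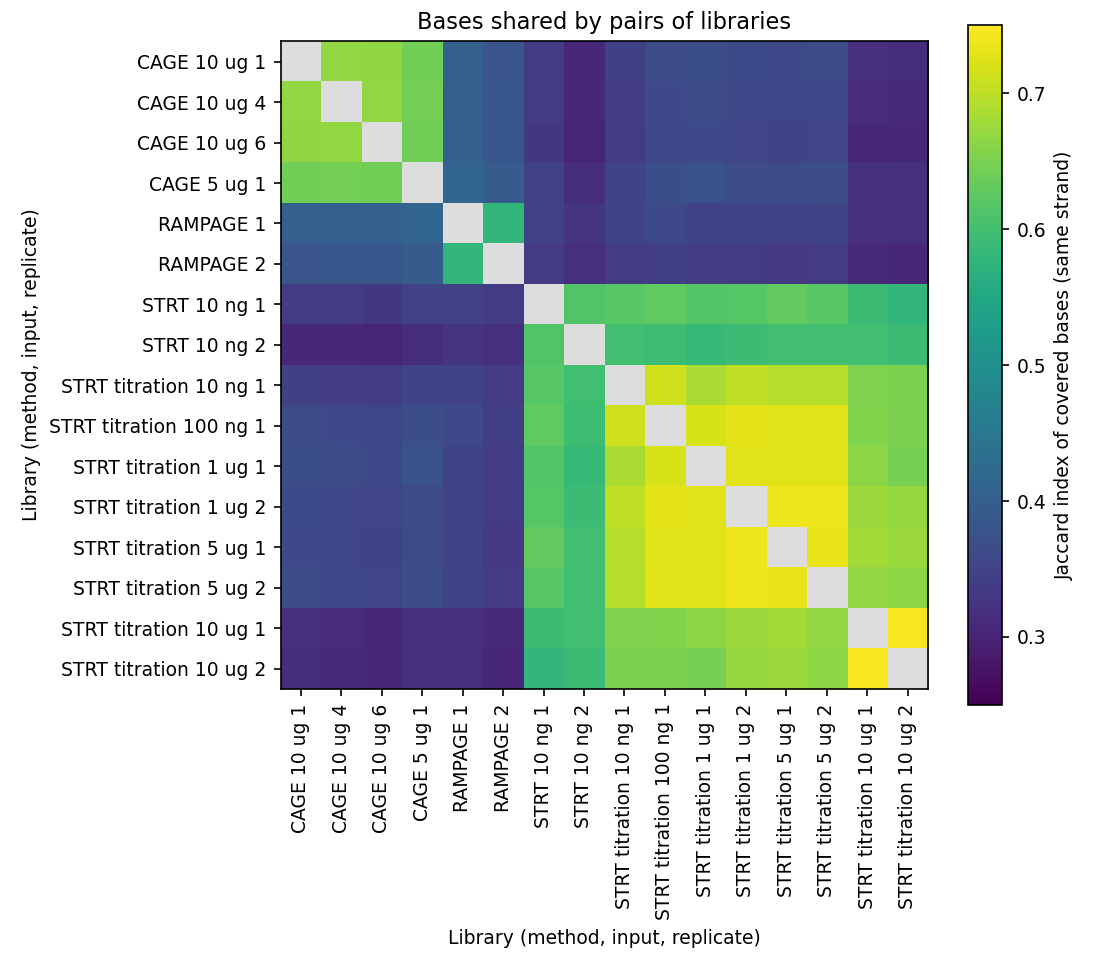
Jaccard index of the bases covered by each pair of 16 libraries, on a color scale from low (dark) to high (light); rows and columns are libraries named by method, input and replicate, and the diagonal is blank. Pairs within a method lie at 0.581 or above, and the 2 titration libraries of 10 µg have an index of 0.745 with each other and 0.663 on average with the other titration libraries.

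Merging the clusters of 16 libraries (4 CAGE, 2 RAMPAGE and 10 STRT) gave 12983 regions. Of these, 3345 had a cluster in all 16 libraries and 3732 in every CAGE and no STRT library. Only 8 had a cluster in every STRT and no CAGE library, a class that requires all 10 STRT libraries. With at least 1 STRT and no CAGE library there were 159. The median RNA-seq value was 9.91 (quartiles 4.62 to 25.1) in the regions of every CAGE and every STRT library that held a window. It was 3.55 (1.92 to 6.99) in those of every CAGE and no STRT library. Oligo capping had a cluster in 78.4% of the 3707 regions of the former class and in 17.0% of the latter, and RAMPAGE, in at least 1 library, in 92.4% and 59.8%. A further 661 regions had a cluster in both RAMPAGE libraries and in no CAGE or STRT library, and 20.9% of them held an RNA-seq window. The median width was 101 bp in these regions. It was 287 bp in those of every CAGE and every STRT library and 229 bp in those of every CAGE and no STRT library. A wider region meets a window or cluster more easily, and the shares were not adjusted for width.

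Regions were named by their score, by rules set before the data were examined. The scores are the authors' and rank clusters within a list; means over libraries describe the named region and assume a scale shared by those lists, which is not given. The highest scores of the CAGE list at 20M reads were 971 on chromosome 19 (13049421 to 13049437, plus strand), 963 on chromosome 19 (49375654 to 49375783, plus strand) and 955 on chromosome 6 (26189325 to 26189340, minus strand). The first had a cluster in all 10 STRT libraries. The others had none in any STRT library and 1 in both RAMPAGE libraries, and they are also the 2 highest among the 3528 CAGE clusters found in every CAGE and no STRT library. Their scores in the 3 CAGE libraries of 10 µg were 979 ± 13.6 and 946 ± 20.8 (SD, n = 3). The next 3 of that class lay on chromosome 14 (103989106 to 103989200, minus strand, 946 ± 25.4), chromosome 19 (344771 to 344837, minus strand, 913 ± 15.7) and chromosome 1 (33815337 to 33815571, minus strand, 927 ± 63.8). RAMPAGE had a cluster on the chromosome 19 region, in both libraries, and none on the other 2.

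Of the 8 STRT clusters found in every STRT and no CAGE library, the highest score, 585, was on chromosome 16 (2014902 to 2015078, plus strand), where neither RAMPAGE library had a cluster. Its score over the 10 STRT libraries was 465 ± 119 (SD, n = 10), and the nearest CAGE cluster at 20M reads on that strand lay 5208 bp away. The next 4 by score were on chromosome 5 (139780982 to 139781081, minus strand, 431 ± 76.1), chromosome 7 (107384467 to 107384556, minus strand, 388 ± 79.2), chromosome 15 (96181554 to 96181789, plus strand, 395 ± 47.9) and chromosome 1 (153508463 to 153508713, minus strand, 449 ± 37.8). Each of these 4 had a cluster in both RAMPAGE libraries, whereas 62.5% of the 8 merged regions of that class had a cluster in at least 1 RAMPAGE library. For these 4 the nearest CAGE cluster on the same strand lay 91259 to 692080 bp away.

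In RAMPAGE at 20M reads, clusters with the top score of 1000 on chromosome 1 (161582212 to 161582320, minus strand) and chromosome 2 (242088971 to 242089024, plus strand) had no CAGE or STRT counterpart. The first was also absent from the same library at 5M reads. The other, on chromosome 1 (155948919 to 155948973, minus strand), had a cluster in all 4 CAGE libraries. In STRT the top scores were 821 on chromosome 11 (207355 to 207426, minus strand), in 3 of 10 STRT libraries, 789 on chromosome 12 (56435656 to 56435954, plus strand), in all 10, and 702 on chromosome 17 (76124755 to 76124874, minus strand), in none of the 10. The 3 highest oligo capping clusters were on chromosome 8 (56986973 to 56987142, minus strand), chromosome 11 (5290985 to 5291263, minus strand) and chromosome 16 (202626 to 202915, plus strand), with scores of 1897234, 378205 and 302815. All 4 CAGE, both RAMPAGE and all 10 STRT libraries and NanoCAGE-XL had a cluster on each of them. Of the 3 windows with the highest RNA-seq values, that on chromosome 11 (5526771 to 5526970, minus strand, value 1391) was found by every CAGE, RAMPAGE and STRT library. Those on chromosome 9 (135894713 to 135894912, plus strand, 1358) and chromosome 6 (74229805 to 74230004, minus strand, 1140) were found by none of them. Oligo capping had a cluster on the former and none on the latter, and the nearest CAGE cluster lay 11185 and 744 bp away.

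The fourth comparison asked whether the amount of RNA put into STRT changed the 5′ ends found. In the titration the number of clusters stayed between 4854 and 5150 from 10 ng to 5 µg (mean 5025, SD 97.2, n = 6). At 10 µg it was 4430 and 4394. The difference between the libraries of 10 µg and the others was -613 clusters on average (exact permutation p = 0.0357, two-sided, the smallest that 28 splits allow, adjusted p = 0.05 over 7 measures; a comparison chosen after seeing the data). The 2 earlier STRT libraries of 10 ng, which are not part of the titration, held 4996 and 4670 clusters. In the titration the share of STRT clusters on CAGE clusters was 98.1% ± 0.10 from 10 ng to 5 µg and 97.6% at 10 µg. Of the 4660 regions with a cluster in all 4 libraries of 1 and 5 µg, 396 (8.50%) had none in either library of 10 µg, and 94.4% of those 396 had a cluster in every CAGE library.

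Over the 8 libraries the number of clusters did not follow the logarithm of input (Pearson r = -0.37, exact permutation p = 0.357; Spearman rho = -0.40, exact permutation p = 0.329; adjusted p = 0.622 and 0.404 over the 4 planned measures). Without the 2 libraries farthest from the median input, those of 10 and 100 ng, r was -0.75 (exact permutation p = 0.10). Without the 2 libraries of 10 µg it was 0.679 (exact permutation p = 0.144), so that its sign rests on them. The covered length (r = -0.312, rho = -0.582), the median width (r = -0.089, rho = -0.335) and the share on CAGE clusters (r = -0.527, rho = -0.57) gave exact permutation p of 0.47, 0.837 and 0.16 for r and 0.136, 0.404 and 0.149 for rho, and adjusted p of 0.622, 0.837 and 0.622 for r and 0.298, 0.404 and 0.298 for rho. Leaving out the 10 and 100 ng libraries gave r of -0.793, -0.802 and -0.496 for these 3 measures (exact permutation p = 0.0778, 0.0667 and 0.30), and rho of -0.956, -0.837 and -0.478 (exact permutation p = 0.0222, 0.0667 and 0.40, unadjusted).

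The authors' scores differed between inputs, although it is not given that their scale is the same in every list. The median score went from 376 at 10 ng through 385 at 100 ng, 400 and 395 at 1 µg, and 406 and 404 at 5 µg to 430 and 429 at 10 µg (r = 0.898, exact permutation p = 0.0018; rho = 0.982, exact permutation p = 0.0004; adjusted p = 0.0126 and 0.0028 over 7 measures). Without the 10 and 100 ng libraries r was 0.86 (exact permutation p = 0.0667) and rho 0.956 (exact permutation p = 0.0222), and without the 10 µg libraries 0.988 (exact permutation p = 0.0056). The number of clusters numbered, read from the highest cluster number of each list, was 7112 at 10 ng and 7991 and 8019 at 10 µg. Its correlation with input was r = 0.73 (exact permutation p = 0.0383, adjusted p = 0.134) and rho = 0.958 (exact permutation p = 0.0008, adjusted p = 0.0028), with r = 0.843 (exact permutation p = 0.0778) and rho = 0.956 (exact permutation p = 0.0222) without the 10 and 100 ng libraries. Without those 2 libraries both relations passed the test by rho and not by r. Both relations were tested within the titration only. The 2 earlier STRT libraries, also of 10 ng, had median scores of 435 and 446, above both lists of 10 µg. They numbered 7247 and 8056 clusters, so that in clusters numbered only replicate 2 of them reached the values of 10 µg. When clusters were kept only at or above the pooled median score of 401, a threshold that passes more clusters where the scores of a list are higher, r of their number with input was 0.981 (exact permutation p = 0.0002). The share on RNA-seq windows did not follow input (r = 0.222, exact permutation p = 0.597, adjusted p = 0.697; rho = -0.097, exact permutation p = 0.819). The median score, the cluster numbers and the share on RNA-seq windows were examined after the data had been seen.

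**Figure D4:**
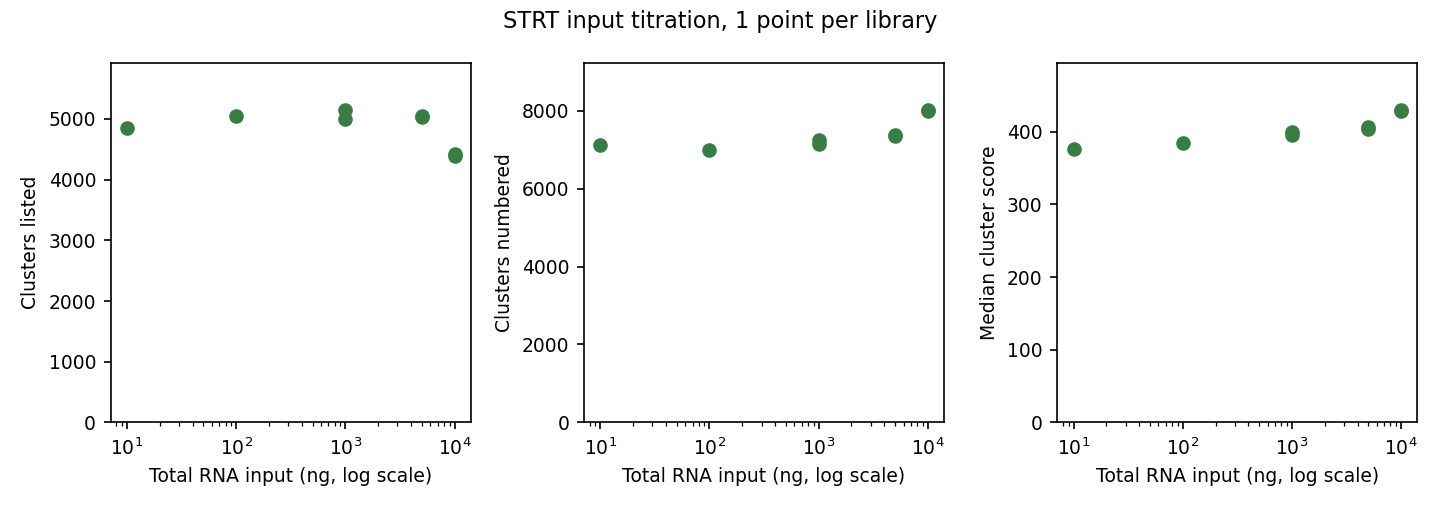
Clusters listed, clusters numbered and median cluster score (vertical axes, from left to right) against total RNA input in ng (horizontal axes, log scale) for the 8 STRT titration libraries, 1 point each. The 2 libraries of 10 µg have the fewest listed clusters (4430 and 4394) and the most numbered clusters (7991 and 8019).

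The last comparisons concerned CAGE input and depth. The CAGE library of 5 µg held 10063 clusters, below the range of the 3 libraries of 10 µg (10442 to 10668, SD 113), and its mean Jaccard index with them was 0.642. With 1 library against 3 there was no test. The RAMPAGE library had 8923 clusters at 5M reads and 8763 at 20M, and 96.3% (95.9 to 96.7) of those at 20M were found at 5M. The STRT library gained clusters with depth, from 4996 to 5412, with 89.9% (89.1 to 90.7) of the deeper list found in the shallower. For CAGE the list at 20M reads pools 3 libraries, so that depth and pooling changed together, and it was found to 97.2%, 95.7% and 96.8% in replicates 1, 4 and 6 at 7M. Median widths were larger at 20M reads in each method: 165 bp against 140 to 147 bp in CAGE, 129 against 110 bp in RAMPAGE and 146 against 137 bp in STRT.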

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

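The comparison of recovery by RNA-seq value, the count of mitochondrial clusters, the depth and transcript level tests for CAGE against STRT and the test of clusters numbered at 10 µg were chosen after the results were seen; the other tests weighed here were set down before their values were computed. No single library was marked by the test for an outlying value in 20 sets of measures (10 each over the 4 CAGE and the 10 STRT libraries, which mix inputs), where chance alone would mark about 1 in 20. That test can miss 2 libraries that stand apart together, as those of 10 µg did in clusters listed and the earlier pair of 10 ng in width.

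From the lower 50% of windows to the highest decile, recovery rose by more points in STRT than in RAMPAGE or CAGE. For CAGE this order depends on the contrast chosen. The lowest and highest deciles stood at 10.8% and 79.4% in CAGE and at 2.92% and 63.9% in STRT. Between these deciles the larger rise was in CAGE. The share of windows recovered was 42.8 percentage points higher in the highest decile than in the lower 50% in RAMPAGE (n = 2) and 54.3 ± 1.45 points higher in STRT (SD, n = 10). The difference between these was -11.52 points (exact permutation p = 0.0152, two-sided, the smallest that 66 splits allow; adjusted p = 0.0228 over 3 pairs of methods). Every STRT library had a steeper rise than both RAMPAGE libraries. CAGE minus STRT was -3.81 points (exact permutation p = 0.003, adjusted p = 0.009), and CAGE minus RAMPAGE 7.71 points (exact permutation p = 0.0667, the smallest that 15 splits allow). These differences were not computed at equal numbers of clusters, so that the unequal length of the lists may contribute to them.

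The oligo capping list held 32 clusters on mitochondrial DNA, 25 on the plus strand and 7 on the minus strand, with 3.98% of the summed score of the list. They count among the 8191 clusters of that list in the overlaps and score quartiles, and no comparison was made of them by themselves. None of the other 20 cluster lists holds a mitochondrial cluster. In those lists, which are sorted by chromosome name as text, 11 to 70 cluster numbers were skipped between chromosomes 9 and X, where mitochondrial and unplaced contigs would stand.

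The first pattern was the large number of CAGE clusters absent from STRT, 4994 at 20M reads. Removal by the authors after numbering cannot account for most of them, since the skipped numbers of the STRT list had room for at most 14.88% (95% Wilson interval 13.9 to 15.9), counted interval by interval along the chromosomes. Depth up to 20M reads does not account for most either, since 9.50% (8.75 to 10.3) of the 5399 clusters absent at 5M reads appeared in the same library at 20M. A lower transcript level is a candidate explanation: a region of every CAGE and no STRT library had a lower RNA-seq value than a region of every CAGE and STRT library with a probability of 0.75 (bootstrap interval 0.737 to 0.762), although only 68.2% and 80.2% of these regions held a window. A filter before numbering stays untested, and the design names no biological group that could be set against these.

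The second pattern was 281 regions with a cluster in every CAGE and every STRT library and none in either RAMPAGE library. The RAMPAGE list at 20M reads had a cluster in 3.56% (1.94 to 6.43) of them. This cannot decide on depth, since that list held no more clusters than the same library's list at reduced depth (8763 against 8923). Removal after numbering was argued against, since skipped numbers had room for at most 11.07% (7.87 to 15.4) of the rest. Start positions shifted by up to 200 bp were argued against as well, with a RAMPAGE cluster that near in 1.78% (0.76 to 4.10). A lower transcript level stays open, because the probability of a lower RNA-seq value than in regions of all 16 libraries was 0.577 (0.541 to 0.612), between the bounds set for and against it. No biological explanation was tested.

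The third pattern was the lower number of STRT clusters at 10 µg within the titration. A low share of listed clusters was not particular to that input. The earlier replicate 2 of 10 ng listed 4670 of 8056 numbered clusters (57.97%), near the 55.44% and 54.79% of the lists of 10 µg. The earlier replicate 1 listed 4996 of 7247 (68.94%). Fewer clusters being called was argued against, since the lists of 10 µg numbered 727 clusters more on average than those of 1 and 5 µg, and both exceeded all 4. For the 396 regions lost at 10 µg, skipped numbers had room for at most 48.23% (43.4 to 53.2) in the list with less room and 50% in the other. Whether removal after numbering took any of them is not shown. The same count gave 30.1% and 31.2% for the 3732 regions of every CAGE and no STRT library. That larger set was counted against the same skipped numbers, which lowers its share, so that these shares cannot be compared. Fewer reads at 10 µg cannot be told apart from removal after numbering. Lost regions had a lower RNA-seq value than kept ones with a probability of 0.599 (0.57 to 0.63), and read totals were not used here. No biological explanation was tested.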

How the results depend on the processing

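The alternatives without the 10 µg libraries, the oligo capping score limit and all those for recovery by RNA-seq value were chosen after seeing the data; the others were set before the data were examined. Method separation kept its direction and its side of 0.05 in all 12 alternatives, with 0.273 to 0.308 when each library was left out. It was lower with equal numbers of clusters (0.229) and by the share of clusters shared (0.208). CAGE held more clusters than STRT in all 19 (5490.5 to 5692 with each library left out). Of these, 1 has no bearing: the pooled median score (9390.8 clusters) lies above the median of every STRT list and below that of every CAGE list, which fixes its outcome. Only the comparison with 2 STRT libraries (5600 clusters), too small to reach 0.05, lost the call. RAMPAGE held fewer than CAGE in all 7, in a design that cannot pass 0.05. Merging within 100 bp changed no direction or call.

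Requiring 50% of the shorter cluster gave overlaps of 82.76% (RAMPAGE on CAGE), 97.43% (STRT on CAGE), 70.21% (CAGE on RAMPAGE) and 65.57% (CAGE on RNA-seq windows), and 95.14% and 96.21% of the pooled CAGE list in replicates 4 and 6. With 5412 clusters per list these overlaps were 56.87%, 52.51%, 56.82% and 39.10%, and oligo capping on CAGE 34.85%, with fewer clusters left to overlap. The upper 50% of oligo capping scores gave 71.15%. CAGE on RNA-seq windows was 73.01% with clusters extended by 50 bp and 71.81% with strand ignored.

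In the titration, a score of at least the pooled median turned r positive for the number of clusters (0.981), covered length (0.976), width (0.67) and share on CAGE (0.252), the score itself rising with input. From 10 ng to 5 µg r was 0.679, 0.592 and 0.18 for the first 3. With the 2 earlier libraries it was 0.305 for covered length, 0.648 for width (permutation p = 0.0405) and -0.667 for the share on CAGE (permutation p = 0.0338); the cause was not tested. Each library left out gave -0.619 to -0.191 for the number and -0.844 to 0.175 for width, where leaving out the 10 ng library gave the only call (-0.844, exact permutation p = 0.0127), and leaving out the 100 ng library (0.175) or replicate 2 of 10 µg (0.105) a positive sign. The replicate block, which leaves only the 6 libraries of 1, 5 and 10 µg, gave -0.753 for the number (exact permutation p = 0.167) and -0.962 for width (exact permutation p = 0.0278), and changed no call for the other 2 measures. The same 6 libraries without the block gave -0.75 and -0.802 (exact permutation p = 0.10 and 0.0667), and the numbers did not pair the libraries.

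The difference in recovery between RAMPAGE and STRT was -13.31 points with the 2 STRT libraries at 5M reads. The exact permutation p there was 0.333, the smallest that 2 against 2 libraries allow in a two-sided test. With each library left out the difference was -11.78 to -11.31 points. Leaving out either RAMPAGE library gave -11.52 with an exact permutation p of 0.0909, the smallest that 11 splits allow. The alternatives planned for transcript starts and gene lists were not run. Unknown depth in the titration and 1 library of oligo capping and NanoCAGE-XL limit what these lists show.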

Other observations

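The results in this part were chosen after seeing the data, and each is given as values. Narrow CAGE clusters were found less often by STRT. Of the 310 CAGE clusters at 20M reads up to 49 bp wide, the 10 STRT libraries had a cluster on 25.4% ± 2.70 (mean ± SD over libraries), against 50.7% ± 2.4 of the 2142 clusters of 250 bp or more. The CAGE libraries themselves recovered 84.7% ± 3.99 (n = 4) of the narrow and 97.6% ± 0.80 of the wide clusters. RAMPAGE (n = 2) recovered 59.5% ± 0.23 and 69.7% ± 1.42. Extending clusters by 50 bp gave STRT 25.9% and 50.7%.

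Promoters that fire in both directions appear as a minus-strand cluster followed within 500 bp by a plus-strand cluster. In the separate libraries, of the CAGE clusters 15.6% ± 0.58 (n = 4) belonged to such a pair, of the RAMPAGE clusters 17.4% ± 0.08 (n = 2) and of the STRT clusters 10.8% ± 0.40 (n = 10). A shorter list has fewer pairs. CAGE lists thinned at random to the median STRT number, with 25 draws per library, had 7.60% ± 0.20 of their clusters in pairs, below STRT in all 10 libraries (difference -3.23 percentage points, exact permutation p = 0.001, two-sided, the smallest that 1001 splits allow). Random thinning drops a cluster without regard to its partner or its RNA-seq value. The regions that STRT lacked were not a random part, since their RNA-seq values were lower. The comparison therefore cannot tell whether STRT favors such pairs.

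Cluster widths separated the 2 STRT sets. The median width was 134 ± 4.24 bp in the 2 libraries at 5M reads and 163 ± 2.71 bp in the 8 titration libraries (exact permutation p = 0.0222, two-sided, the smallest that 45 splits allow; adjusted p = 0.0667 over 6 measures). CAGE, at 142 ± 3.56 bp (n = 4), lay between them, so that the sign of the CAGE to STRT difference in width depends on the STRT set. The mean Jaccard index was 0.696 for pairs of titration libraries and 0.604 for pairs of a titration library and an earlier one.

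Overlap moved in different ways with the authors' score in the lists where it is bounded. From the lowest to the highest quartile of score, STRT clusters at 20M reads overlapped CAGE in 96.8%, 99.1%, 99.1% and 98.6% of cases, and RAMPAGE in 84.6%, 87.2%, 89.4% and 88.0%. RAMPAGE clusters overlapped CAGE in 83.0%, 84.0%, 89.0% and 82.7%, and STRT in 47.7%, 55.3%, 60.1% and 53.2%. The CAGE clusters were covered by STRT in 47.4%, 54.4%, 53.8% and 50.9%, and lay on RNA-seq windows in 66.0%, 70.3%, 71.2% and 71.8%.

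Skipped cluster numbers were spread along the chromosomes, with a longest run of 7 to 20 in any list. In CAGE, RAMPAGE and STRT the longest runs of 2 or more lists overlapped. In the 4 CAGE libraries it ended at 68598903 or 68598908 on chromosome 6, and STRT lists shared runs on chromosomes 1, 7 and 17. In RAMPAGE it stood on chromosome 11 in all 3 lists: replicate 1 at 5M reads skipped 20 numbers between 65266642 and 65271746, a stretch of 5.1 kb, and replicate 2 skipped 19 from 65266568 on. These regions were singled out after their values were seen. The share of numbered clusters that were listed was 93.4% in CAGE and 92.6% in RAMPAGE at 20M reads, 74.0% in STRT and 51.1% in NanoCAGE-XL.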
